A study of Homo sapiens with 14 samples.

How the data were processed

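Total RNA of MDA-MB-231 cells was made into stranded libraries after ribosomal RNA depletion, per the labels' protocols, and 14 libraries were analysed, 2 for each of 7 groups. The submitters' processing notes name CASAVA 1.8.4, TopHat2 2.0.5, HTSeq 0.6.0, edgeR without a version, R 3.0.0 and the genome build hg19. The role and order of these tools, the gene annotation, the strand setting of the counting, the filter on genes and the kind of scaling are not given in the sources used here. The deposited table holds 13734 genes by symbol, 1 column per library, with 0 columns of other samples and 0 lines that name no gene. Its name calls the values CPM, and the plan fixed before the data were examined assumed CPM. The columns, however, summed to between 903627 and 1098052, where CPM of the plain read totals would give 1 total for every library. The deposited values were therefore treated as a scaled signal, RPM of an effective library size set by the authors (scaled RPM). Only 3 genes stayed under a value of 1 in every library, so genes of low level are largely not analysed here.

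Within each column every value was a whole multiple of 1 step, so whole reads were recovered for 100% of the values at a tolerance of 0.01. The recovered reads gave depths of 15741695 to 37311326 reads per library (median 23539829), and the scaling factors behind the deposited values ranged from 0.911 to 1.11. TMM (trimmed mean of M-values) factors from edgeR lay close to them. They were 1.1048 against 1.10665 for YAP/TAZ siRNA mix 2 replicate 1 and 0.91088 against 0.910704 for JQ1 replicate 1. The deposited values thus look like CPM with TMM scaling, although the sources used here do not say so. Between 1 and 60 genes per library were at 0. A single read was worth between 0.0276 and 0.0602 of the deposited unit, so a gene at the filter limit of 1 rested on few reads and its fold change is imprecise.

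Groups and replicate numbers came from the sample titles. The values were transformed to log2(value + 1) and filtered to the 13674 genes with a value of at least 1 in at least 2 libraries. One limma model (limma 3.58.1, R 4.3.3) with a term for each of the 7 groups was fitted to all 14 libraries, with moderated variances that follow the mean, 7 residual and 13.2 prior degrees of freedom, and a median residual SD of 0.0865. P-values were two-sided and adjusted by Benjamini-Hochberg within each comparison, at a threshold of 0.05. The comparisons were YAP/TAZ siRNA (mean of mix 1 and mix 2) and BRD siRNA (mean of mix A and mix B) against control siRNA, JQ1 against DMSO, DMSO against control siRNA, YAP/TAZ siRNA against BRD siRNA, and the JQ1 effect against each knockdown effect. Replicate pairs differed by more than sampling noise in every group, with a chi-square per gene of 3.44 to 10.6, so no replicate was a copy of the other replicate of its group.

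The gene lists were written from textbook knowledge before the data were examined: YAP/TAZ target genes, Hippo pathway and TEAD factors, AP-1 factors, DNA replication, mitosis, histone genes, BET inhibitor response genes, transcription elongation, ribosome biogenesis and MYC targets, NF-kB and inflammatory cytokines, interferon-stimulated genes, extracellular matrix and adhesion, actin cytoskeleton and SRF targets, cholesterol synthesis, p53 targets, lysosome and autophagy, integrated stress and unfolded protein response, hypoxia and glycolysis, luminal, leukocyte, and fibroblast and endothelial markers. A list of mitochondrial genome genes matched 0 genes and was not tested. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists within each comparison, and again with an estimated correlation and with fry. Overlaps were set against independent lists, and unchanged groups were simulated 100 times for comparisons with shared controls. After the data were seen, 2 comparisons with shared controls were also fitted against 1 control siRNA library each, in both orders, with 6 residual degrees of freedom. For the overlaps, a set of 342 cell cycle and histone genes was written from textbook knowledge after the data were seen and before its overlap was computed.

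The genes named in the text follow a rule fixed before the data were examined. It takes the targeted genes, CYR61, CTGF, ANKRD1, AXL, MYC and HEXIM1, and for each main comparison the 6 largest rises and 6 largest falls among called genes whose treated libraries all lay on one side of the controls and whose mean in the higher group was at least 5. It adds up to 4 members of each list with the largest moderated statistic, the 8 genes lowest in all 3 main comparisons, and the 4 largest differences each way between effects. Not every gene that the rule takes is reported here.

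The alternatives, chosen before the data were examined unless said otherwise, were pseudocounts of 0.25 and 4, no filter and a filter at 5, median-ratio, upper-quartile and quantile scaling, a replicate block, no variance trend, only the libraries of a comparison in the model, each siRNA mix alone, DMSO as the control of the knockdowns, each library left out in turn, and edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads. RPM without the deposited scaling, overlaps without cell cycle and histone genes, and families of metallothionein, small nucleolar and ribosomal protein genes with 3 noncoding RNAs were added after the data were seen, and so was each mix alone as an alternative for lists and named genes, planned only for counts and overlaps. The edgeR quasi-likelihood test called 5746 genes higher and 4870 lower after YAP/TAZ siRNA, 5034 and 5126 after BRD siRNA, and 5253 and 5077 after JQ1. DESeq2 called 5069 and 4937, 4656 and 4947, and 4739 and 5054.

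The procedure was tested on simulated data, 10 draws per comparison with 200 changed genes each, drawn from the means and depths of the real libraries. Genes changed 2-fold were recovered in 99.6% of cases for YAP/TAZ siRNA (13212 genes tested), 99.4% for BRD siRNA (13211), 99.4% for JQ1 (13226) and 100% for YAP/TAZ against BRD siRNA (13230). Genes changed 1.5-fold were recovered in 93.6%, 94.0%, 91.6% and 97.0% of cases. False calls made up 8.81%, 7.65%, 4.45% and 6.19% of calls, so the rate exceeded 5% in 3 of these comparisons, and the highest draws reached 12%, 10.8%, 6.22% and 11.2%. These shares depend on how many genes are unchanged. Only 200 genes were changed per draw, whereas 10793 of 13674 were called in the real YAP/TAZ comparison, so the shares need not hold for real calls. Genes of the lowest means were not among those changed, so the recovery rates leave them out. Of 210 unchanged lists, 0 were called in each comparison at the preset correlation. Genes were drawn independently of each other here, whereas the estimated correlation was 0.696 for the real mitosis list and 0.579 for the histone list. The simulation therefore does not test list calls where genes vary together. Genes changed 8-fold came out at a median log2 fold change of 2.87 to 2.89, below the true 3.

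Of the 13734 symbols, 12440 matched an Ensembl gene identifier. No coordinates are printed, since the reference used here for names is of another build than hg19. Figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.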

Results

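RNA was sequenced from MDA-MB-231 cells, an established human breast cancer cell line, in 14 libraries that fall into 7 groups of 2. YAP1 (YAP) and WWTR1 (TAZ) are transcriptional co-activators at the end of the Hippo pathway, which reach DNA mainly through the TEAD factors. BRD2 and BRD3 belong to the BET proteins, readers of acetylated histones, and JQ1 is a small molecule that displaces BET proteins from acetylated lysines. The groups were control siRNA, 2 siRNA mixes against YAP and TAZ (mix 1 and mix 2, 48 h), 2 siRNA mixes against the BRD genes (mix A and mix B, 72 h), DMSO, and JQ1 (1 µM, 24 h). The series title sets the question, the part of BET proteins in transcription that depends on YAP and TAZ. The labels give no harvest time for the control siRNA or the DMSO libraries, so both knockdowns were set against the same 2 control siRNA libraries although their times differ. The libraries held 15741695 to 37311326 reads in genes (median 23539829), and values are given as scaled RPM, reads divided by an effective library size. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. The labels do not say that replicates are separate cultures, so p-values measure the spread between the 2 libraries of a group, which may be technical. Each siRNA mix is a group of its own, so the spread between mixes of a target enters no p-value of the model of 7 groups. Of 13674 tested genes, 8981 differed between the YAP/TAZ mixes and 6843 between the BRD mixes (limma adjusted p under 0.05).

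The targeted transcripts YAP1, WWTR1, BRD2 and BRD3 were lower in the libraries labelled with siRNA against them. YAP1 was at 182 ± 11.4 (SD, n = 2) with control siRNA and 21.6 ± 2.34 (n = 4) with YAP/TAZ siRNA, 8.11-fold lower (log2 fold change -3.02, SE 0.0579, limma adjusted p = 5.57e-20). WWTR1 went from 131 ± 6.29 (n = 2) to 14.5 ± 2.17 (n = 4), 8.57-fold lower (log2 fold change -3.10, SE 0.0558, limma adjusted p = 2.87e-20). After BRD siRNA, BRD3 went from 31.1 ± 1.96 (n = 2) to 9.76 ± 0.742 (n = 4; log2 fold change -1.58, SE 0.0748, limma adjusted p = 7.82e-14). BRD2 fell less, from 252 ± 0.52 to 175 ± 21.6 (-0.53, SE 0.0557, limma adjusted p = 2.36e-08). BRD2 mRNA rose after JQ1, which acts on the proteins, from 249 ± 11.1 in DMSO to 937 ± 25.1 (log2 fold change 1.91, SE 0.0643, limma adjusted p = 3.5e-16). BRD3 mRNA rose slightly after JQ1 (0.28, SE 0.0864, limma adjusted p = 0.00625).

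The perturbations also moved each other's targets. YAP1 fell after BRD siRNA (-0.85, SE 0.0579, limma adjusted p = 2.57e-11) and after JQ1 (-0.84, SE 0.0668, adjusted p = 3.36e-10), with means of 100.3 ± 5.84 (n = 4) and 103.5 ± 2.79 (n = 2). WWTR1 fell after JQ1 (-0.33, SE 0.0644, adjusted p = 0.000115), while after BRD siRNA its log2 fold change of -0.12 missed the threshold (limma adjusted p = 0.0582). That WWTR1 result was unstable: it passed without control siRNA replicate 2 (0.0369) and without mix A replicate 2 (0.0409), with every other scaling tried (0.000418 to 0.0421), edgeR (0.0372) and DESeq2 (0.0362), the mixes went opposite ways (150.2 ± 4.98 with mix A and 96.3 ± 2.44 with mix B), and against the DMSO libraries it turned to 0.55 (adjusted p = 1.29e-08). After YAP/TAZ siRNA, BRD2 rose by 0.18 (adjusted p = 0.00623), from 252 ± 0.52 to 345 ± 0.63 with mix 1 and 236 ± 1.60 with mix 2, where it did not pass (-0.09, adjusted p = 0.183). BRD3 passed narrowly after YAP/TAZ siRNA (0.17, limma adjusted p = 0.0414). That BRD3 call was lost without control siRNA replicate 2 (0.11, adjusted p = 0.296), mix 1 replicate 2 (0.0962) or mix 2 replicate 1 (0.134), with median-ratio scaling (0.11), with DESeq2 (0.156) and with mix 2 alone (0.222).

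**Figure D1:**
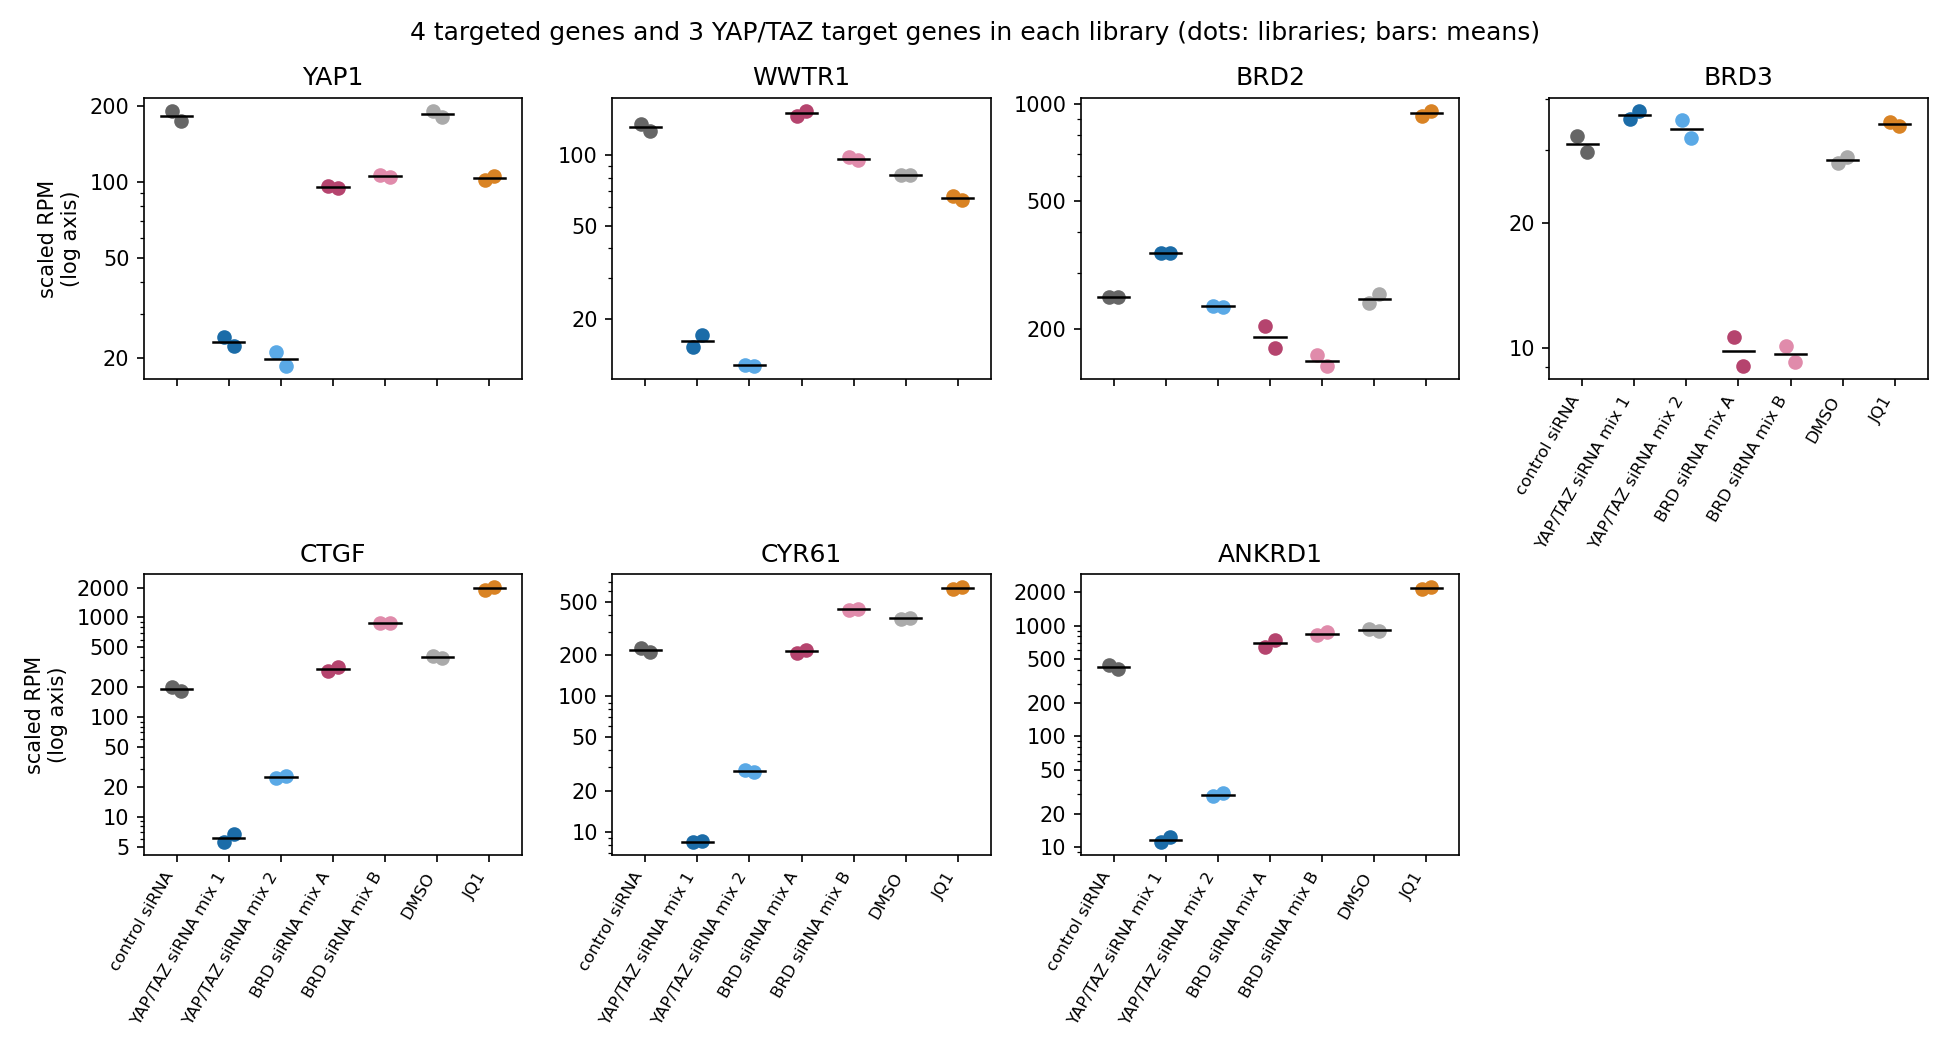
Scaled RPM (log axis) of the targeted genes YAP1, WWTR1, BRD2 and BRD3 and of the YAP/TAZ target genes CTGF, CYR61 and ANKRD1 in the 14 libraries, where dots are libraries and bars are group means. CTGF lay at 6.12 with YAP/TAZ siRNA mix 1 and 24.9 with mix 2, below 193 with control siRNA, and at 1962 with JQ1, above 404 in DMSO.

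YAP/TAZ siRNA was compared with control siRNA to ask which transcripts change when YAP and TAZ are depleted. CTGF (CCN2), CYR61 (CCN1) and ANKRD1, widely used readouts of YAP/TAZ activity, fell by far the most among the fixed genes. CTGF went from 193 ± 11.6 (SD, n = 2) to 6.12 ± 0.809 with mix 1 (n = 2) and 24.9 ± 1.02 with mix 2 (n = 2), 14.3-fold lower over both (log2 fold change -3.84, SE 0.0608, limma adjusted p = 4.97e-21). CYR61 was 13.3-fold lower (-3.73, SE 0.0463, adjusted p = 1.04e-22) and ANKRD1 21.4-fold lower (-4.42, SE 0.0611, adjusted p = 4.78e-22). AXL, a receptor tyrosine kinase, fell (-1.51, limma adjusted p = 6.87e-16), as did MYC (-0.72, adjusted p = 6.34e-11), while HEXIM1, an inhibitor of the elongation kinase P-TEFb, rose (1.01, adjusted p = 9.65e-13). The largest falls under the rule for named genes were HIST1H2AJ (-4.48), CCNE2 (-4.43, SE 0.0915), ANKRD1, HIST1H2BM (-4.33), FAM111B (-4.29) and CDC25A (-4.11). CCNE2, a cyclin of S phase entry, went from 62.1 ± 7.85 (n = 2) to 2.04 ± 1.01 (n = 4). The largest rises were GDF15 (3.79, SE 0.116), RASD1 (3.69), EPHB6 (3.59), TFF3 (3.53), SPINK4 (3.46) and SLC14A1 (3.36); GDF15, a secreted stress-response factor, went from 3.28 ± 0.722 to 58.6 ± 10.5. Against the DMSO libraries TFF3 (5.34) and SPINK4 (5.26) rose further and HEXIM1 less (0.58), and of 101 named genes of this comparison 22 had log2 fold changes over 1.5 times larger, 6 over 1.5 times smaller and 1 of the other sign. Histone genes form a near-identical family, and how reads shared among its members were counted is uncertain.

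Proliferation genes fell as groups after YAP/TAZ siRNA. All 44 DNA replication genes fell (median log2 fold change -2.21, camera adjusted p = 5.6e-20; adjusted p = 0.0754 with an estimated correlation), among them CDC6 (-3.39), MCM10 (-3.82) and FEN1 (-2.51). All 42 histone genes fell (median -2.74, camera adjusted p = 4.82e-19; adjusted p = 0.182 with an estimated correlation), for example HIST1H2AG (-3.80). All 38 mitosis genes fell (median -1.88, camera adjusted p = 3.44e-16; adjusted p = 0.182 with an estimated correlation), among them KIF23 (-3.14) and AURKB (-2.28). All 38 genes of ribosome biogenesis and MYC targets fell (median -1.36, camera adjusted p = 3.44e-16; adjusted p = 0.0754 with an estimated correlation), including the nucleolar factors DDX21 (-2.56) and DKC1 (-2.13). Of 22 YAP/TAZ target genes, 14 fell, 4 rose and 4 did not pass (median -0.71, camera adjusted p = 0.000433; adjusted p = 0.0754 with an estimated correlation), and AMOTL2 (-1.99) fell next to the genes above. Of 28 genes of the actin cytoskeleton and SRF targets, 19 fell and 3 rose (median -0.43, camera adjusted p = 0.00133; adjusted p = 0.0952 with an estimated correlation), led by ANLN (-1.94) and DIAPH3 (-2.13). ANLN also stands in the mitosis list.

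Other groups rose. Of 43 genes of lysosome and autophagy, 36 rose and 3 fell (median 0.46, camera adjusted p = 1.11e-05; adjusted p = 0.182 with an estimated correlation), with WIPI1 (1.89), SQSTM1 (1.38) and the cathepsin CTSD (1.55) as examples. Among 36 interferon-stimulated genes, 27 rose and 3 fell (median 0.63, camera adjusted p = 0.000214; adjusted p = 0.0754 with an estimated correlation), including OAS1 (2.14), IRF9 (1.60) and IFI35 (1.51), while IFIT5 fell (-1.11). Against the DMSO libraries the interferon list had 32 higher and 3 lower, with a median of 1.61. Among 26 cholesterol synthesis genes, 19 rose and 3 fell (median 0.47, camera adjusted p = 0.00631; adjusted p = 0.182 with an estimated correlation), for example HMGCS1 (1.16) and TM7SF2 (1.81). The mixes differed in this list (camera adjusted p = 1.74e-08 for mix 1 against mix 2; adjusted p = 0.044 with an estimated correlation): with mix 1 alone 23 were higher and 1 lower (median 0.97, camera adjusted p = 5.45e-07), and with mix 2 alone 9 were higher and 10 lower (median -0.02, camera adjusted p = 0.549), so the call rested on mix 1. HMGCS1 was at 2.13 with mix 1 and 0.20 with mix 2. Against DMSO the cholesterol median was 0.87. Of 30 genes of hypoxia and glycolysis, 21 rose and 4 fell (median 0.32, camera adjusted p = 0.00751; adjusted p = 0.248 with an estimated correlation); NDRG1 (2.48) and ALDOC (1.83) rose and the glucose transporter SLC2A1 fell (-0.92). That hypoxia call was lost against the DMSO libraries (17 higher, 8 lower, median 0.49, camera adjusted p = 0.0761) and with mix 2 alone, where 13 were higher and 8 lower (median 0.06, camera adjusted p = 0.579), while mix 1 alone gave 23 higher and 2 lower (median 0.57, camera adjusted p = 2.99e-05; adjusted p = 0.12 with an estimated correlation).

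Markers of other cell types were read as measured facts beside these groups. Of 14 luminal epithelial markers, 12 rose and 0 fell (median 1.16, camera adjusted p = 0.000433; adjusted p = 0.0952 with an estimated correlation), led by AGR2 (2.74), TFF3 (3.53), SPDEF (2.23) and the keratin KRT19 (1.54); against DMSO 11 were higher and 2 lower (median 1.76). All 4 leukocyte markers tested rose, LYZ (1.90), CD68 (0.92), CD14 (1.23) and CD8A (0.62), with a median of 1.07 (camera adjusted p = 0.0267; adjusted p = 0.182 with an estimated correlation). The deposited table holds only 4 of the 14 leukocyte markers written, 3 of 13 fibroblast and endothelial markers and 14 of 18 luminal markers. With control siRNA, CD14 (0.69 and 1.02) and CD8A (0.59 and 1.08) lay near the filter limit of 1. The leukocyte call was lost with DESeq2 (0.0572), against DMSO (camera adjusted p = 0.054) and with mix 1 alone (camera adjusted p = 0.0768), where CD8A was at -0.03 (limma adjusted p = 0.879) against 1.27 with mix 2. The 3 fibroblast and endothelial markers tested also rose, PDGFRB (1.84), PECAM1 (1.88) and KDR (0.30, limma adjusted p = 0.00343), but the list was not called (median 1.84, camera adjusted p = 0.0724). The KDR call was lost without control siRNA replicate 1 (adjusted p = 0.0597), with quantile normalization (0.687) and with DESeq2 (0.0779), and its sign turned against DMSO (-0.56). KDR was at -0.22 with mix 1 alone (limma adjusted p = 0.0521) and at 0.82 with mix 2.

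The remaining lists were not called after YAP/TAZ siRNA, and their members went both ways. The 11 AP-1 factors had 4 higher and 4 lower (median -0.03, camera adjusted p = 0.674), with FOSL1 at -2.16 and JUND at 1.21. The 13 BET inhibitor response genes had 6 higher and 7 lower (median -0.43, camera adjusted p = 0.437), with the cell cycle kinase CDK6 at -1.42 (-0.59 against DMSO) and BCL2 at -2.59. The 23 genes of the Hippo pathway and TEAD factors had 9 higher and 12 lower (median -0.28, camera adjusted p = 0.397), with AJUBA at -0.94 and WWC1 at -1.11. For NF-kB and inflammatory cytokines 12 of 28 were higher and 9 lower (median 0.07, camera adjusted p = 0.93), with IL11 at -2.09 and ICAM1 at 1.94. The mixes differed in the NF-kB list, with 21 genes higher and 2 lower with mix 1 than with mix 2. The median difference was 0.54 (camera adjusted p = 6.32e-06, or 0.044 with an estimated correlation). Extracellular matrix and adhesion genes had 24 of 42 higher and 15 lower (median 0.28, camera adjusted p = 0.534), with PLAU at -3.03 and ITGAV at -1.83. The 30 genes of the integrated stress and unfolded protein response had 12 higher and 13 lower (camera adjusted p = 0.538), with SHMT2 at -1.42 and DDIT4 at 1.77. The 23 p53 target genes had 11 higher and 6 lower (median 0.08, camera adjusted p = 0.437), with AEN at -2.95 and TP53INP1 at 1.86. The 24 transcription elongation genes had 12 higher and 8 lower (median 0.14, camera adjusted p = 0.534), with ELL at 0.63 (0.20 against DMSO) and LEO1 at 0.60. The sign of the median changed between scalings for AP-1, NF-kB and the stress response, with mix 1 alone for AP-1 and the stress response, and with mix 2 alone for NF-kB and extracellular matrix. Against DMSO it changed for AP-1 (0.03) and the stress response (0.04), while NF-kB (0.49) and p53 targets (0.55) lay higher and elongation genes lower (0.02), with none of these lists called. Adjusted over the list alone, the counts were equal to those over all genes except 10 higher in the Hippo list and 13 higher in the stress response list.

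Across 13674 tested genes, limma called 5889 higher and 4904 lower after YAP/TAZ siRNA, of which 1305 and 1145 changed by at least 2-fold (2128 and 1788 against DMSO). Called the same way with each mix alone were 4144 higher and 3390 lower genes, against 2373 and 1641 for independent lists. Another 992 were called opposite ways, 8 of them at 2-fold or more with each mix. Fold changes with mix 1 and mix 2 correlated at 0.761 across genes, which are not independent replicates. Unchanged groups simulated against the same 2 control libraries gave a correlation of 0.4998, a covariance of 0.00525 against 0.557 observed, and 0.05 genes called the same way with each mix against 7534. With no gene changed, almost none can pass the threshold, so the simulated count does not show what the shared controls add. With each mix set against a different one of the 2 control libraries, in both orders, the correlation was 0.751 and 0.734, the covariance 0.555 and 0.543, and 6954 and 6803 genes were called the same way. What both control libraries have in common is not removed by this. With mix 1 alone the YAP/TAZ target list had 16 lower (median -0.81, camera adjusted p = 5.7e-06; adjusted p = 0.0449 with an estimated correlation) and with mix 2 alone 14 lower and 5 higher (median -0.35, camera adjusted p = 0.00669; adjusted p = 0.167 with an estimated correlation). In simulated data 8.81% of the calls in this comparison were false, above the nominal 5%.

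BRD siRNA was compared with control siRNA to ask what changes when the BET genes are depleted. PLAT, tissue plasminogen activator, showed the largest rise under the rule for named genes, from 145 ± 4.49 (SD, n = 2) to 3287 ± 165 with mix A (n = 2) and 712 ± 7.15 with mix B (n = 2; log2 fold change 3.39, SE 0.0486, limma adjusted p = 1.95e-21). The nuclear noncoding RNA NEAT1 (3.12), NDRG1 (2.80), ARHGAP5-AS1 (2.69), G0S2 (2.66) and KDR (2.65) followed. ARHGAP5-AS1 is an antisense gene and its value is uncertain, since the strand setting of the counting is not given in the sources used here. The largest falls were E2F2 (-3.77, SE 0.125, limma adjusted p = 2.73e-16), HIST1H2BE (-3.63), E2F8 (-3.62), HIST1H2BA (-3.56), CCNE1 (-3.53) and LAPTM5 (-3.44). E2F2, E2F8 and CCNE1 act in S phase entry; E2F8 went from 33.2 ± 2.14 (n = 2) to 1.78 ± 0.129 (n = 4). LAPTM5, a lysosomal membrane protein, went from 61.1 ± 0.018 to 4.85 ± 1.33. Against the DMSO libraries G0S2 was at only 0.64 and LAPTM5 at -1.45, and of 102 named genes of this comparison 16 had log2 fold changes over 1.5 times smaller, 8 over 1.5 times larger and 8 of the other sign.

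The YAP/TAZ readouts did not fall after BRD siRNA. CTGF rose (1.42, SE 0.0608, limma adjusted p = 1.48e-14), with 304 ± 17.1 in mix A and 879 ± 1.02 in mix B against 193 ± 11.6 in the control (each n = 2). ANKRD1 (0.86, SE 0.0611, adjusted p = 5.51e-11) and CYR61 (0.47, SE 0.0463, adjusted p = 9.16e-09) were higher over both mixes, but CYR61 with mix A alone was at -0.04 (adjusted p = 0.507) and with mix B at 0.98. Against the DMSO libraries, CTGF stayed higher (0.36, limma adjusted p = 1.79e-05), while CYR61 (-0.29, adjusted p = 6.64e-06) and ANKRD1 (-0.26, adjusted p = 0.000614) were lower. AXL rose (0.31, adjusted p = 3.7e-05), although it was at -0.12 with mix A alone (adjusted p = 0.107) and quantile normalization turned it to -0.03, and HEXIM1 rose (1.27, limma adjusted p = 3.07e-14; 0.84 against DMSO). MYC differed between the mixes, -0.20 with mix A and 0.49 with mix B, and averaged 0.15 (limma adjusted p = 0.0162). The MYC call was lost without control siRNA replicate 1 (adjusted p = 0.0514), control siRNA replicate 2 (0.0648), mix A replicate 2 (0.0635) or mix B replicate 1 (0.056), with upper-quartile scaling (0.0521), without scaling (0.699) and with only these libraries in the model (0.0556). Against DMSO, MYC was lower (-0.50, adjusted p = 2.1e-08).

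Proliferation genes fell after BRD siRNA too. All 44 DNA replication genes fell (median -1.82, camera adjusted p = 6.84e-19; adjusted p = 0.214 with an estimated correlation), among them E2F1 (-3.07), UHRF1 (-2.85) and MCM10 (-3.14). Of 42 histone genes 41 fell (median -2.41, camera adjusted p = 1.42e-16; adjusted p = 0.241 with an estimated correlation), for example HIST1H4B (-2.39). Of 38 mitosis genes 37 fell (median -1.29, camera adjusted p = 4.41e-13; adjusted p = 0.296 with an estimated correlation), led by ANLN (-2.45), KIF2C (-2.33) and AURKA (-1.80). In ribosome biogenesis and MYC targets 28 of 38 fell and 2 rose (median -0.43, camera adjusted p = 4.1e-05; adjusted p = 0.241 with an estimated correlation), with DKC1 (-1.22) and TCOF1 (-1.18); against DMSO 37 fell and 1 rose (median -0.95). NF-kB and inflammatory cytokines had 17 of 28 lower and 5 higher (median -0.41, camera adjusted p = 0.0366; adjusted p = 0.241 with an estimated correlation); CSF2 (-2.87, or -1.02 against DMSO) and BIRC3 (-1.88, or -0.65) fell and CSF1 (1.87, or 3.67) rose. Actin cytoskeleton and SRF targets had 17 of 28 lower and 6 higher (median -0.29, camera adjusted p = 0.0462; adjusted p = 0.265 with an estimated correlation), including TAGLN (-2.13) and TAGLN2 (-1.79). Without control siRNA replicate 2 the NF-kB (0.0527) and actin (camera adjusted p = 0.0607) calls were lost, and the actin call also without mix B replicate 1 (0.0501). The NF-kB call was lost as well with pseudocount 4 (0.0594), the filter at 5 (0.1), edgeR (0.21) and DESeq2 (0.354), the actin call with only these libraries in the model (0.059), and both without scaling (0.0709 and 0.0631) and against DMSO (0.476 and 0.105). With a single mix, the NF-kB call was lost with mix A (0.0672) and with mix B (0.0625), and the actin call with mix A (camera adjusted p = 0.132).

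Lysosome and autophagy genes rose after BRD siRNA, 35 of 43 with 3 lower (median 0.52, camera adjusted p = 9.98e-07; adjusted p = 0.241 with an estimated correlation), including the autophagy receptor SQSTM1 (2.11) and GABARAPL2 (1.40). Of 30 hypoxia and glycolysis genes, 21 rose and 3 fell (median 0.32, camera adjusted p = 0.000318; adjusted p = 0.241 with an estimated correlation), with ADM (1.62, but 0.37 against DMSO) and BNIP3 (1.37); the median was 0.55 with mix A alone. Transcription elongation genes rose, 17 of 24 with 3 lower (median 0.32, camera adjusted p = 0.0213; adjusted p = 0.214 with an estimated correlation); AFF4 (0.91) and CTR9 (0.73) rose and LARP7 fell (-0.73). The elongation call was lost with edgeR (0.0532) and against DMSO (camera adjusted p = 0.412).

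The YAP/TAZ target list had 12 of 22 higher and 6 lower after BRD siRNA and was not called (median 0.18, camera adjusted p = 0.135), with NT5E at 2.06, MYOF at 0.81 and TGFB2 at -0.98; edgeR (0.0454) and DESeq2 (0.0109) called it higher. Against the DMSO libraries the balance of the YAP/TAZ target list turned, with 8 higher and 12 lower (median -0.28, camera adjusted p = 0.464). Extracellular matrix and adhesion genes had 25 of 42 higher and 14 lower (median 0.33, camera adjusted p = 0.136), with ITGA2 at 1.77 and MMP1 at 2.27 (1.41 against DMSO), and were called higher with edgeR (0.0454) and DESeq2 (0.00905), while the median was 0.07 with mix B alone. The 36 interferon-stimulated genes had 11 higher and 18 lower (median -0.19, camera adjusted p = 0.235), with OAS3 at -3.16 and IFIT2 at 1.46; against DMSO 20 were higher and 8 lower, with a median of 0.37 (camera adjusted p = 0.0478; adjusted p = 0.301 with an estimated correlation). Of the Hippo and TEAD genes 13 were higher and 5 lower (median 0.21, camera adjusted p = 0.223), with TAOK2 at 0.81 and TEAD4 at -0.91. AP-1 factors had 4 higher and 3 lower (median 0.11, camera adjusted p = 0.565) and BET inhibitor response genes 6 higher and 7 lower (median -0.45, camera adjusted p = 0.565), with CDK6 at -1.70 (-0.87 against DMSO). Cholesterol synthesis genes had 7 higher and 11 lower (median 0.01, mean -0.09, camera adjusted p = 0.686), with ACAT2 at -1.78, but against DMSO 17 higher and 8 lower (median 0.57, camera adjusted p = 0.0592). The stress response list had 15 higher and 13 lower (median 0.14, mean -0.06, camera adjusted p = 0.879), with EDEM1 at 1.73 and TRIB3 at -2.09, and p53 targets 11 higher and 8 lower (median 0.14, camera adjusted p = 0.64), with CCNG1 at -1.49. The medians of AP-1 and cholesterol synthesis changed sign between scalings and with mix A alone. Against DMSO the stress response median turned to -0.02, those of AP-1 (0.24) and p53 targets (0.47) lay higher, and those of the Hippo (0.04) and BET inhibitor response lists (-0.17) lay nearer to 0, with none of these lists called.

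Of the markers of other cell types after BRD siRNA, 7 of 14 luminal markers were lower and 4 higher (median -0.29, or -0.15 against DMSO, camera adjusted p = 0.183 and 0.716), with EPCAM at -1.51. Leukocyte markers had 3 of 4 lower (median -0.51, camera adjusted p = 0.213), with LYZ at -1.52 (-0.37 against DMSO) and CD8A at -0.33 (limma adjusted p = 0.033). CD8A was at -0.13 without control siRNA replicate 2 (adjusted p = 0.475) and at -0.53 without control siRNA replicate 1 (adjusted p = 0.00722), and its call was lost without mix A replicate 2 (0.0793) and mix B replicate 1 (0.148). The CD8A call was also lost with pseudocount 4 (0.0583), quantile normalization (0.237), only these libraries in the model (0.0678) and DESeq2 (0.0537), and with mix B alone (0.21). Of 3 fibroblast and endothelial markers 1 was higher and 1 lower (median -0.16, mean 0.70, camera adjusted p = 0.686), with a median of 0.46 with mix A alone, -0.53 with mix B alone and 0.61 against DMSO, where all 3 were higher (camera adjusted p = 0.119). Counts adjusted over the list alone were equal to those over all genes in every list of this comparison.

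Limma called 5143 genes higher and 5136 lower after BRD siRNA, 684 and 1131 of them by at least 2-fold (1241 higher against DMSO). With each mix alone 3804 were higher and 3711 lower, against 1795 and 1753 for independent lists, and 555 were called opposite ways, 2 of them at 2-fold or more. Mix A and mix B correlated at 0.827 across genes, against 0.5005 for simulated unchanged groups, with a covariance of 0.439 against 0.00528, and 7515 genes were called the same way with each mix against 0.07 simulated. As for the YAP/TAZ mixes, that simulated count does not show what the shared controls add. With a different control library for each mix, in both orders, the correlation was 0.794 and 0.805, the covariance 0.428 and 0.433, and 6711 and 6813 genes were called the same way. False calls made up 7.65% of the calls in data simulated for this comparison.

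JQ1 was compared with DMSO to ask what BET inhibition changes within 24 h. EFR3B showed the largest rise under the rule for named genes, from 1.92 ± 0.132 to 98.7 ± 4.17 (SD, n = 2 each; log2 fold change 5.10, SE 0.127, limma adjusted p = 4.94e-18). CLU (4.56), C9orf169 (4.22), PEG10 (4.03), NEAT1 (3.82) and BAIAP3 (3.79) followed; CLU encodes the secreted chaperone clusterin. HAS2, a hyaluronan synthase, went from 42.9 ± 1.31 to 0.619 ± 0.365 (-4.78, SE 0.107, limma adjusted p = 1.16e-18), next to HIST1H2BM (-4.89), FAT3 (-4.49), HIST1H2AJ (-3.74), HIST1H2BA (-3.71) and HIST1H2BE (-3.62). The YAP/TAZ readouts rose: CTGF from 404 ± 15.3 to 1962 ± 104 (2.28, SE 0.0702, limma adjusted p = 9.28e-17), ANKRD1 from 917 ± 24.0 to 2192 ± 72.6 (1.26, SE 0.0706, adjusted p = 1.22e-12) and CYR61 from 376 ± 2.88 to 632 ± 14.8 (0.75, SE 0.0534, adjusted p = 6.05e-11). AXL rose (0.75, limma adjusted p = 8.52e-10), as did HEXIM1 (1.52, adjusted p = 1.83e-14), which is widely used as a marker of BET inhibition. MYC fell (-0.34, limma adjusted p = 3.83e-05), from 153 ± 2.44 to 121 ± 2.37.

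All 38 mitosis genes fell after JQ1 (median -2.58, camera adjusted p = 5.83e-19; adjusted p = 0.277 with an estimated correlation), led by AURKA (-3.20), AURKB (-3.17) and TOP2A (-3.03). All 44 DNA replication genes fell (median -1.87, camera adjusted p = 1.03e-17; adjusted p = 0.137 with an estimated correlation), among them FEN1 (-2.35) and MCM3 (-2.05). Histone genes fell in 41 of 42 cases (median -2.33, camera adjusted p = 3.76e-17; adjusted p = 0.277 with an estimated correlation), with HIST1H3H at -2.98. Ribosome biogenesis and MYC targets had 35 of 38 lower and 2 higher (median -0.95, camera adjusted p = 5.27e-10; adjusted p = 0.137 with an estimated correlation), with TCOF1 (-1.98) and DKC1 (-1.70). NF-kB and inflammatory cytokines had 21 of 28 lower and 3 higher (median -0.55, camera adjusted p = 5e-04; adjusted p = 0.137 with an estimated correlation), including the cytokine IL11 (-1.79), NFKB1 (-1.22) and BIRC2 (-1.09). Lysosome and autophagy genes rose, 30 of 43 with 4 lower (median 0.42, camera adjusted p = 8.41e-05; adjusted p = 0.351 with an estimated correlation), with ULK1 (2.25), SQSTM1 (1.72) and NEU1 (1.71). The integrated stress and unfolded protein response rose, 22 of 30 with 5 lower (median 0.47, camera adjusted p = 0.00109; adjusted p = 0.277 with an estimated correlation), with DDIT4 (3.36) and asparagine synthetase ASNS (2.67). Hypoxia and glycolysis genes rose, 20 of 30 with 5 lower (median 0.48, camera adjusted p = 0.00118; adjusted p = 0.277 with an estimated correlation), with NDRG1 (2.45) and ALDOC (2.18).

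The other lists were not called after JQ1. YAP/TAZ target genes had 10 of 22 higher and 6 lower (median 0.04, camera adjusted p = 0.589), with CTGF at 2.28, FJX1 at -2.53 and TGFB2 at -1.72. BET inhibitor response genes had 4 of 13 higher and 8 lower (median -0.34, camera adjusted p = 0.431), with SERPINI1 at 2.78 and E2F2 at -3.29. Only 1 of the 13 did not pass, while 73.9% of all tested genes were called. Camera asks for a shift in 1 direction, so a list whose members move both ways can go uncalled. The missing call therefore does not show that these genes did not respond, here or after the knockdowns. Extracellular matrix genes had 14 of 42 higher and 23 lower (median -0.28, camera adjusted p = 0.166), with EDN1 at -3.08 and PLAU at -2.12. Interferon-stimulated genes had 18 of 36 higher and 14 lower (median 0.18, camera adjusted p = 0.546), with ISG15 at 1.55 and OAS3 at -1.77. AP-1 factors had 5 higher and 4 lower (median 0.25, camera adjusted p = 0.539), with JUND at 2.41, and Hippo and TEAD genes 9 higher and 9 lower (median -0.05, mean 0.02, camera adjusted p = 0.847), with VGLL3 at 1.72. Actin and SRF targets had 8 higher and 13 lower (median -0.14, camera adjusted p = 0.507). Cholesterol synthesis had 11 higher and 9 lower (median 0.10, camera adjusted p = 0.54), with TM7SF2 at 3.29, and p53 targets 12 higher and 8 lower (median 0.48, camera adjusted p = 0.472), with the cell cycle inhibitor CDKN1A at 2.88. Transcription elongation genes had 10 higher and 5 lower (median 0.06, camera adjusted p = 0.539). The sign of the median changed between scalings for the YAP/TAZ target, Hippo, leukocyte and elongation lists. Adjusted over the list alone, the counts differed only for NF-kB (22 lower) and extracellular matrix (24 lower).

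Luminal markers had 6 of 14 higher and 3 lower after JQ1 (median 0.14, camera adjusted p = 0.372), with KRT19 at 3.11, KRT8 at 2.02 and SPDEF at -2.11; edgeR (0.038) and DESeq2 (0.00769) called the list higher. Leukocyte markers had 2 of 4 higher and 1 lower (mean -0.05, camera adjusted p = 0.951). Among them CD14 was at 0.38 (limma adjusted p = 0.0235), a call lost without DMSO replicate 1 (0.176) or JQ1 replicate 1 (0.143), with pseudocount 4 (0.0802) and with quantile normalization (0.0693). Fibroblast and endothelial markers had 2 of 3 higher (median 0.46, camera adjusted p = 0.539). Limma called 5136 genes higher and 4968 lower after JQ1, 1171 and 1223 of them by at least 2-fold. In data simulated for this comparison 4.45% of calls were false.

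**Figure D2:**
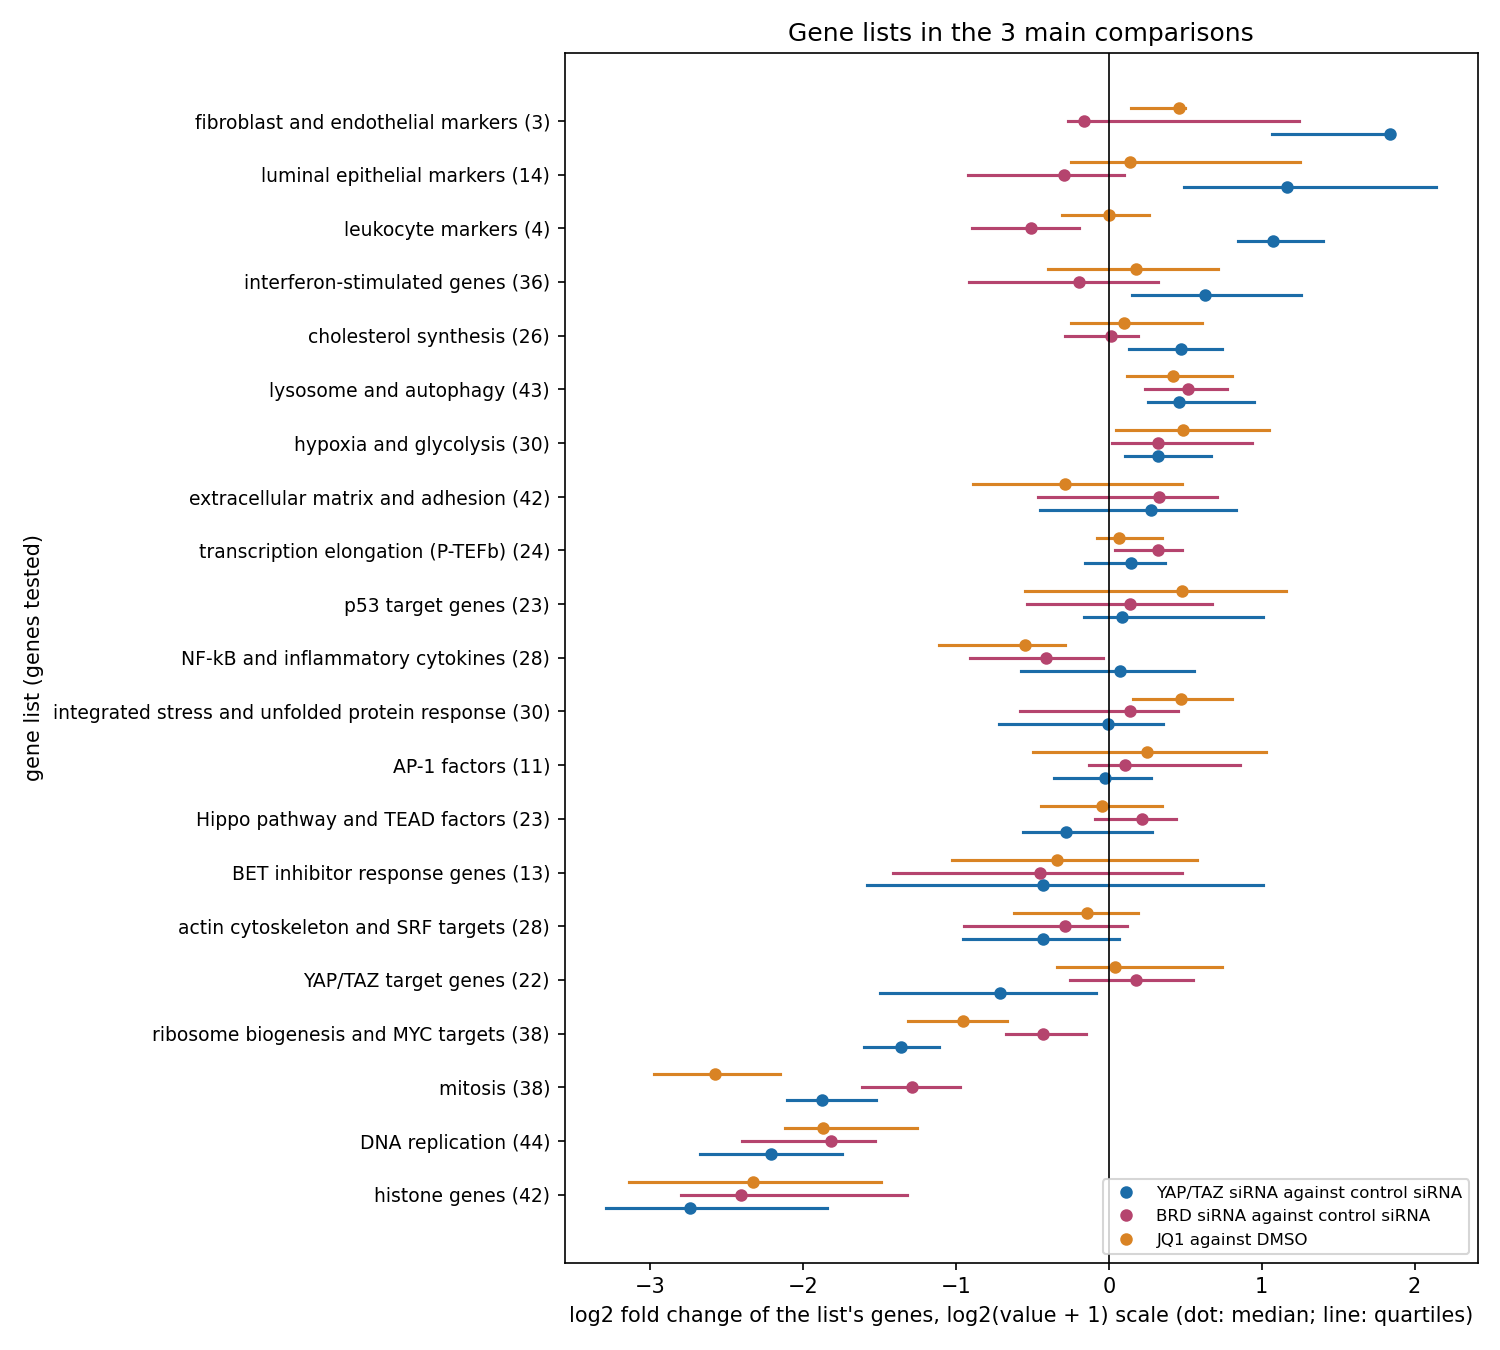
Median log2 fold change (points) and quartiles over members (bars) of 21 gene lists after YAP/TAZ siRNA, BRD siRNA and JQ1, each against its own controls. The medians of DNA replication (-2.21, -1.82 and -1.87), histone and mitosis genes lay lowest, and the YAP/TAZ target list lay at -0.71 after YAP/TAZ siRNA, 0.18 after BRD siRNA (-0.28 against DMSO) and 0.04 after JQ1, the last of which changed sign between scalings.

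The YAP/TAZ target genes were then followed across the perturbations. The 14 members that fell after YAP/TAZ siRNA, a set picked by that result, fell with each mix alone. After BRD siRNA 9 of these were higher (AMOTL2, ANKRD1, ASAP1, AXL, CTGF, CYR61, IGFBP3, MYOF and PTPN14), 2 were lower (FJX1 and TGFB2) and 3 did not pass. With mix A alone 8 were higher and 4 lower, with mix B alone 10 and 2, and 6 were higher with both (ANKRD1, ASAP1, CTGF, IGFBP3, MYOF and PTPN14). F3 and LATS2 were lower with mix A and higher with mix B. After JQ1 7 were higher (AMOTL2, ANKRD1, AXL, CTGF, CYR61, F3 and MYOF), 3 were lower (FJX1, IGFBP3 and TGFB2) and 4 did not pass. Against DMSO in place of control siRNA, BRD siRNA left 5 of the 14 higher and 7 lower. In DMSO itself 8 of the 14 were higher than with control siRNA and 3 lower, so the direction after BRD siRNA depended on the control for part of the set.

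Overlaps of calls asked whether the perturbations moved the same genes. Of 1145 genes at least 2-fold lower after YAP/TAZ siRNA, 991 were also called lower after BRD siRNA and 990 after JQ1, against 430.1 and 416 for independent lists, and 57 and 69 were called higher. Of 1305 genes at least 2-fold higher after YAP/TAZ siRNA, 705 (54.0%) were called higher after BRD siRNA and 786 (60.2%) after JQ1, against 490.8 and 490.2 for independent lists, and 313 and 200 were called lower. At 2-fold or more in each, 604 genes were lower after both YAP/TAZ siRNA and JQ1, which share no libraries, against 102 for independent lists. The numbers were 500 against 94.7 for YAP/TAZ and BRD siRNA (915 with DMSO as their control) and 581 against 101 for BRD siRNA and JQ1. Genes higher by at least 2-fold in both numbered 400 against 112 for YAP/TAZ siRNA and JQ1, 247 against 65.3 for the knockdowns (749 with DMSO), and 313 against 58.6 for BRD siRNA and JQ1 (496 with DMSO). All 3 perturbations lowered 401 genes by at least 2-fold, against 8.47 for independent lists, and 233 of these (58.1%) belong to a set of 342 cell cycle and histone genes written from textbook knowledge after the data were seen. E2F8, an E2F family repressor, was among them (-3.13, -3.62 and -3.55 after YAP/TAZ siRNA, BRD siRNA and JQ1), with HIST1H2AJ, HIST1H2BM, HIST1H3J, HIST1H2BE, HIST1H2BA, HIST1H2AH and HIST1H3B. All 3 raised 145 genes by at least 2-fold, against 5.59 (337 with DMSO as the control of the knockdowns). With DMSO as their control, the knockdowns share the DMSO libraries with JQ1, which can add to the overlap. The values for independent lists printed here belong to the main controls and not to the counts with DMSO.

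Fold changes correlated across genes, which are not independent replicates, at 0.482 between the knockdowns, 0.541 between YAP/TAZ siRNA and JQ1, and 0.630 between BRD siRNA and JQ1. The knockdowns share their control libraries, and simulated unchanged groups against those controls gave a correlation of 0.667 and a same-sign share of 73.2%, against 66.0% observed. The observed covariance was 0.271 against 0.00527 simulated, a difference of 0.265. Called the same way in both knockdowns were 6203 genes, against 0.12 in the simulations. No gene was changed in the simulations, so almost none could pass the threshold. The simulated count therefore does not measure what the shared controls add to the 6203. With 1 of the 2 control libraries for each knockdown, in both orders, the correlation was 0.442 and 0.481, the covariance 0.254 and 0.271, the same-sign share 64.1% and 65.9%, and 5387 and 5604 genes were called the same way. A feature that both control libraries share would still add to these values. For YAP/TAZ siRNA and JQ1 the simulated correlation was 0.00107.

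**Figure D3:**
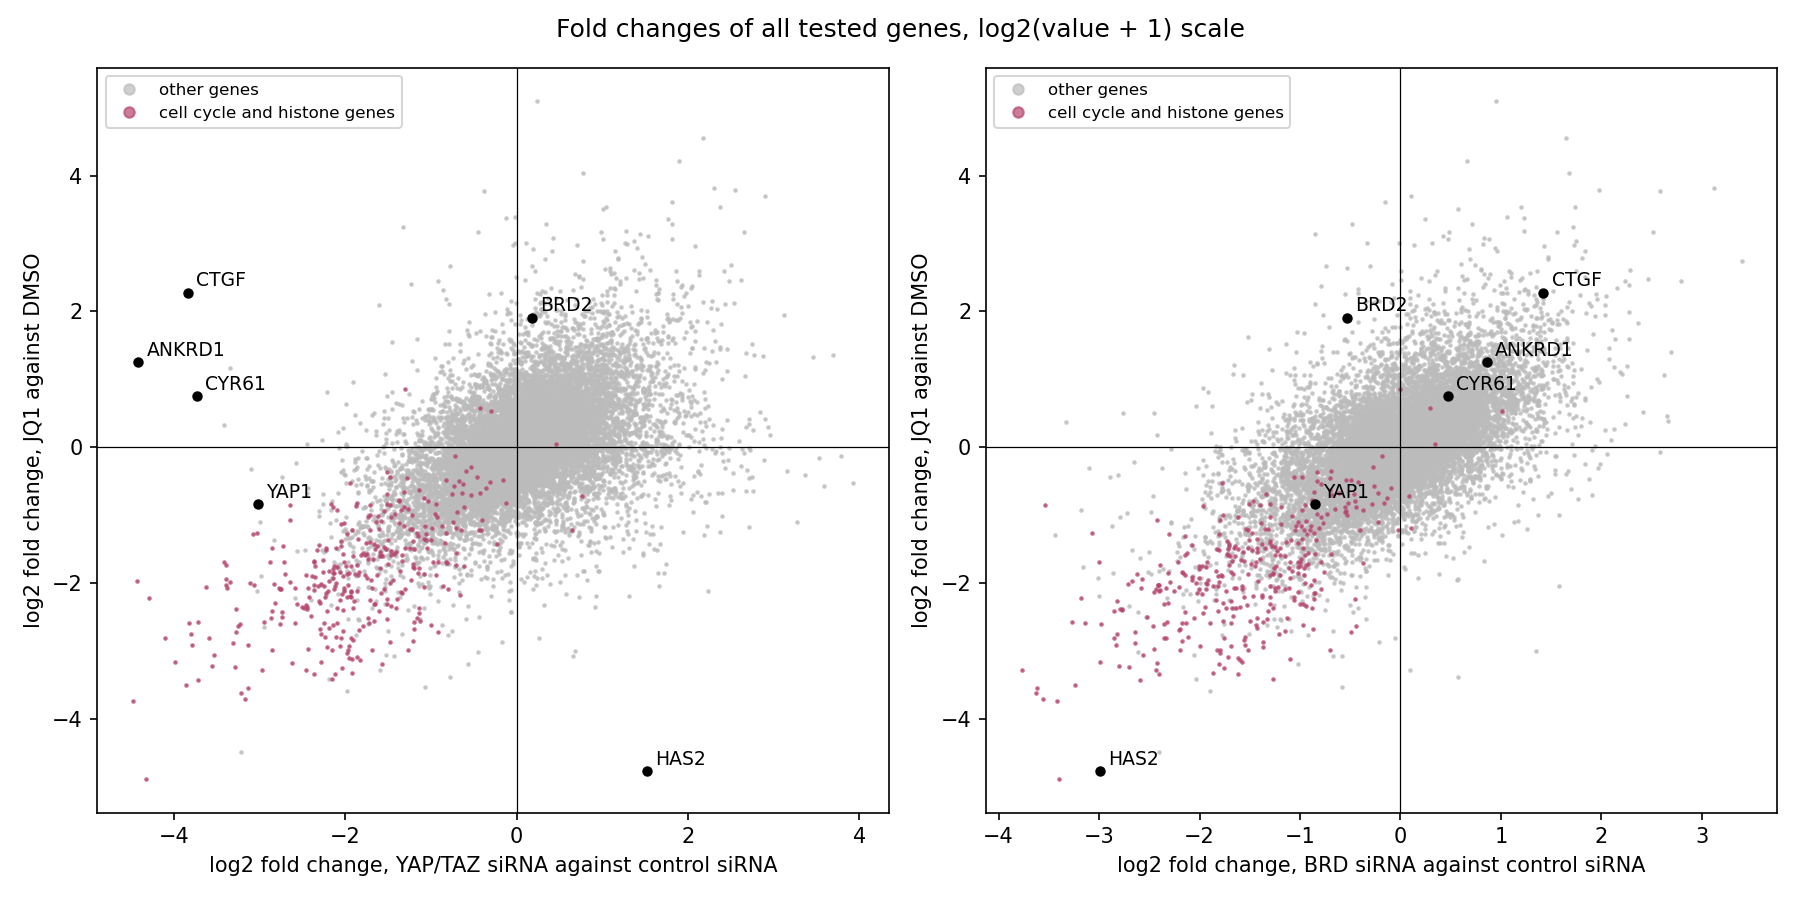
Log2 fold change of each tested gene after YAP/TAZ siRNA (left) or BRD siRNA (right) on the horizontal axis and after JQ1 on the vertical axis, with cell cycle and histone genes coloured and CTGF, CYR61, ANKRD1, BRD2, HAS2 and YAP1 marked. Across genes the correlations were 0.541 and 0.630, and CTGF lay at -3.84 after YAP/TAZ siRNA, 1.42 after BRD siRNA and 2.28 after JQ1.

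Direct tests of one effect against another showed where the perturbations parted. In YAP/TAZ siRNA against BRD siRNA the control cancels, but the time does not (48 h and 72 h), so target and time cannot be told apart. The 2 knockdowns differed most for ANKRD1 (-5.28), CTGF (-5.26) and CYR61 (-4.20), each with limma adjusted p = 1.48e-25, and for DDAH1 (-4.01) on one side. On the other side stood NOX5 (5.56), TIMP4 (4.90), EPHB6 (4.83) and CD96 (4.51). The YAP/TAZ target list lay lower after YAP/TAZ siRNA than after BRD siRNA, with 17 of 22 genes lower and 5 higher (median -1.10, camera adjusted p = 0.000256; adjusted p = 0.0796 with an estimated correlation). Interferon-stimulated genes lay higher, 25 of 36 with 8 lower (median 0.99, camera adjusted p = 0.000427; adjusted p = 0.0839 with an estimated correlation), as did luminal markers, 13 of 14 (median 1.56, camera adjusted p = 2.67e-05; adjusted p = 0.0796 with an estimated correlation). The 4 leukocyte markers tested all lay higher (median 1.31, camera adjusted p = 0.0121, or 0.173 with an estimated correlation), and 22 of 26 cholesterol synthesis genes with 1 lower (camera adjusted p = 0.000148, or 0.0983). All 38 genes of ribosome biogenesis and MYC targets lay lower (median -0.94, camera adjusted p = 6.04e-12; adjusted p = 0.0796 with an estimated correlation). Mitosis genes lay lower too, 30 of 38 with 5 higher (camera adjusted p = 0.000427, or 0.583 with an estimated correlation). Limma called 5617 genes higher and 5505 lower, 1472 and 648 by at least 2-fold. In data simulated for this comparison 6.19% of calls were false. List tests in these comparisons and in DMSO against control siRNA were added after the data were seen, and not every list called in them is reported here.

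The JQ1 effect exceeded the BRD siRNA effect most for EFR3B (4.15), CLIC3 (3.99), RNF224 (3.77) and TPPP (3.77), and BRD2 differed by 2.44 (limma adjusted p = 7.45e-15). SLCO4A1 (-4.36), FAM196B (-3.97), EVI2A (-3.38) and SORCS3 (-2.96) lay on the other side. CTGF rose more after JQ1 than after BRD siRNA (0.86, limma adjusted p = 1.18e-07), while the MYC effect lay lower (-0.48, adjusted p = 2.67e-05). JQ1 and the knockdowns have different controls, so the difference between DMSO and control siRNA enters these tests. Against DMSO, MYC was at -0.34 after JQ1 and at -0.50 after BRD siRNA, the other order, and the BRD mixes disagreed (-0.197 and 0.489). SORCS3 was at 3.41 and 2.89 with control siRNA but at 19.6 and 18.6 in DMSO, so its difference rests largely on the controls. Mitosis genes lay lower after JQ1, 37 of 38 with 1 higher (median -1.24, camera adjusted p = 5.04e-15; adjusted p = 0.335 with an estimated correlation), as did extracellular matrix genes, 28 of 42 with 10 higher (median -0.58, camera adjusted p = 0.000261; adjusted p = 0.321 with an estimated correlation). Stress response genes lay higher, 19 of 30 with 3 lower (camera adjusted p = 0.00147), as did luminal markers, 8 of 14 with 1 lower (0.0115). Ribosome biogenesis and MYC targets lay lower, 27 of 38 with 3 higher (3.6e-06), but against DMSO their median was -0.95 after both JQ1 and BRD siRNA. With an estimated correlation each of these 3 lists had an adjusted p of 0.321. The YAP/TAZ target list was not called (9 higher, 8 lower, median -0.11, camera adjusted p = 0.418). Between JQ1 and YAP/TAZ siRNA the largest differences were CTGF (6.11), ANKRD1 (5.68), EFR3B (4.85) and CPA4 (4.56) upward, and HAS2 (-6.29), NOX5 (-4.38), SPDEF (-4.35) and EPHB6 (-4.16) downward. HAS2 went from 61.4 ± 4.15 (n = 2) to 179 ± 29.6 (n = 4) with YAP/TAZ siRNA and to 6.93 ± 1.48 (n = 4) with BRD siRNA. The YAP/TAZ target list lay higher with JQ1 than with YAP/TAZ siRNA, 14 of 22 with 6 lower (median 0.91, camera adjusted p = 0.00984; adjusted p = 0.282 with an estimated correlation). Stress response genes lay higher too, 19 of 30 with 3 lower (camera adjusted p = 0.000452, or 0.282). Mitosis genes lay lower, 31 of 38 with 1 higher (7.27e-07, or 0.394). So did 4 of 4 leukocyte markers (0.0196, or 0.282) and 10 of 14 luminal markers with 3 higher (0.0266, or 0.287). Limma called 4125 genes higher and 4093 lower for JQ1 against BRD siRNA, and 4232 and 4430 for JQ1 against YAP/TAZ siRNA.

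DMSO was compared with control siRNA because both serve as background. CTGF (1.06), ANKRD1 (1.12) and CYR61 (0.77) were higher in DMSO (limma adjusted p = 1.17e-10, 6e-11 and 2.69e-10), as were MYC (0.64) and HEXIM1 (0.43), while WWTR1 was lower (-0.67) and AXL did not pass (-0.08, adjusted p = 0.271). Interferon-stimulated genes were lower in DMSO, 26 of 36 with 3 higher (median -0.68, camera adjusted p = 5.06e-09), and this call held with an estimated correlation (adjusted p = 0.0272). Ribosome biogenesis and MYC targets were higher, 37 of 38 (median 0.54, camera adjusted p = 1.62e-13; adjusted p = 0.0888 with an estimated correlation). NF-kB genes were lower, 16 of 28 with 4 higher (median -0.40, camera adjusted p = 0.000806; adjusted p = 0.0944 with an estimated correlation), and cholesterol synthesis genes too, 17 of 26 with 3 higher (median -0.44, camera adjusted p = 4.9e-05; adjusted p = 0.108 with an estimated correlation). DNA replication genes were higher, 35 of 44 with 1 lower (median 0.31, camera adjusted p = 2.7e-06; adjusted p = 0.357 with an estimated correlation). So were 31 of 42 histone genes (camera adjusted p = 2.7e-06, or 0.485 with an estimated correlation) and 25 of 38 mitosis genes (0.000122, or 0.531), with 0 lower in each. Luminal markers were lower in DMSO, 7 of 14 with 3 higher (median -0.27, camera adjusted p = 0.043, or 0.357 with an estimated correlation). The YAP/TAZ target list was higher, 13 of 22 with 5 lower (median 0.22, camera adjusted p = 0.00642; adjusted p = 0.135 with an estimated correlation). Limma called 3931 genes higher and 3478 lower, 106 and 349 of them by at least 2-fold.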

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

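The fits of each mix against control siRNA and of one mix against the other were planned, but the single-mix tests of MYC, PDGFRB and WWTR1 were chosen only after the results were seen, since these genes were picked because their mixes went opposite ways. With the YAP/TAZ mixes, 992 genes passed the limma threshold in opposite directions against control siRNA, 8 of them at 2-fold or more with each mix. With the BRD mixes 555 genes did so, 2 of them at 2-fold or more. Among the named genes, MYC differed by -0.686 (log2, mix A minus mix B; limma adjusted p = 7.36e-09), being at -0.197 with mix A and 0.489 with mix B, 2 libraries each. PDGFRB differed by 1.68 (0.463 with mix A and -1.22 with mix B, adjusted p = 1.14e-09). WWTR1 differed by 0.635 (0.198 with mix A and -0.437 with mix B, adjusted p = 6e-08), so its average over the mixes describes neither of them. The cause was not tested.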

How the results depend on the processing

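RPM without the deposited scaling, single mixes for lists and named genes, separate control libraries for the 2 sides of an overlap, and the overlaps and families named as added, were chosen only after the results were seen; the other settings were planned. Over 306 named gene results and 6213 values under other settings, 6156 kept their direction and their side of the threshold, 30 lost the call, 9 gained one and 18 changed sign. The counts of called genes in the 3 main comparisons stayed within 1.5 times under all settings. Leaving out a library gave 5414 to 5799 higher and 4602 to 4801 lower genes after YAP/TAZ siRNA, 4701 to 5141 and 4717 to 5113 after BRD siRNA, and 4706 to 4751 and 4513 to 4595 after JQ1. The lone library left in such a group was assumed to vary like the others. Other settings gave 4834 to 6469 and 4481 to 5440, 4199 to 5458 and 4474 to 6112, and 4582 to 5412 and 4570 to 5427. Counts at 2-fold moved more. The cause of these changes was not tested. Depth limits the precision of low genes, where a single read was worth up to 0.0602 of the unit.

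With pseudocount 0.25, DMSO against control siRNA had 164 genes higher by at least 2-fold (106 as reported) and 559 lower (349), and 222 genes were higher in all 3 main comparisons (145). With pseudocount 4, the counts at 2-fold were 715 higher after YAP/TAZ siRNA (1305), 439 higher and 686 lower after BRD siRNA (684 and 1131), 749 higher after JQ1 (1171), and 59 higher and 156 lower in DMSO. They were 757 higher for YAP/TAZ against BRD siRNA (1472), 505 higher and 380 lower for JQ1 against BRD siRNA (960 and 588), and 731 lower for JQ1 against YAP/TAZ siRNA (1248). Shared higher genes were 126 for the knockdowns (247), 197 for YAP/TAZ siRNA and JQ1 (400), 185 for BRD siRNA and JQ1 (313) and 65 in all 3.

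Without the deposited scaling, 2570 genes were higher in DMSO than with control siRNA (3931), 68 by at least 2-fold, and 408 were lower by at least 2-fold for YAP/TAZ against BRD siRNA (648). The median of all genes moved with the scaling: after YAP/TAZ siRNA to 0.13 with upper-quartile scaling and 0.12 without scaling, and after BRD siRNA to -0.11 without scaling. On recovered reads, edgeR gave at 2-fold 1992 higher genes after YAP/TAZ siRNA, 1759 lower after BRD siRNA, 207 higher and 741 lower in DMSO, and 1475 higher for JQ1 against BRD siRNA. Its shared genes were 450 higher for the knockdowns, 763 higher for YAP/TAZ siRNA and JQ1, 883 lower (581) and 516 higher for BRD siRNA and JQ1, and 290 higher in all 3. DESeq2 gave 1776 lower after BRD siRNA, 204 higher and 683 lower in DMSO, 395 and 678 shared higher, 906 lower and 482 higher for BRD siRNA and JQ1, 251 higher in all 3, and 5 lists higher after BRD siRNA (3).

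With DMSO as the control of the knockdowns, 2128 genes were higher and 1788 lower by at least 2-fold after YAP/TAZ siRNA and 1241 higher after BRD siRNA. Shared genes were 915 lower (500) and 749 higher for the knockdowns, 496 higher for BRD siRNA and JQ1, and 337 higher in all 3, where the knockdowns and JQ1 share the DMSO libraries. Signs changed for KDR after YAP/TAZ siRNA (-0.56), and after BRD siRNA for WWTR1 (0.55), CYR61 (-0.29), ANKRD1 (-0.26), MYC (-0.50), PTX3 (-0.17, from 1.97), PDGFRB (0.61), SAMD9L (0.33, from -1.38) and AGR2 (1.25, from -1.14). AXL after BRD siRNA was at -0.0323 with quantile normalization. With a single mix, signs changed after YAP/TAZ siRNA for KDR (-0.22) and CD8A (-0.0282) with mix 1 and BRD2 (-0.0947) with mix 2, and after BRD siRNA with mix A for WWTR1 (0.20), CYR61 (-0.0402), AXL (-0.12), MYC (-0.20) and PDGFRB (0.46).

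Camera with an estimated correlation called 0 lists higher and 0 lower in each main comparison, against 6 and 6 after YAP/TAZ siRNA, 3 and 6 after BRD siRNA and 3 and 5 after JQ1. At an unadjusted p under 0.05 it gave 2 higher and 4 lower, 1 and 1, and 0 and 3. Fry, which does not compare a list with other genes, called 9 higher and 10 lower after YAP/TAZ siRNA, 9 higher and 11 lower after BRD siRNA, and 11 higher and 8 lower after JQ1.

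With the replicate number as a block, 5894 genes were higher and 4905 lower after YAP/TAZ siRNA, 5145 and 5131 after BRD siRNA, and 5150 and 4967 after JQ1, and no call among the named gene results or lists changed. Deviations of libraries with the same number correlated between -0.373 and 0.254 over 21 pairs of groups, 7 of them over 0.1. No consistent pairing by number was seen, but a pairing between some of the groups is not excluded.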

Other observations

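The tests of metallothionein, ribosomal protein and small nucleolar families and of MALAT1, the removal of cell cycle and histone genes, and all tests of the rise of CTGF, CYR61 and ANKRD1 were chosen only after the results were seen. Metallothionein genes, which bind zinc and copper, rose after JQ1 in 4 of 4 cases (median log2 fold change 2.28, camera adjusted p = 0.00162; adjusted p = 0.0754 with an estimated correlation). After BRD siRNA 3 rose and 1 fell (median 2.13, camera adjusted p = 0.0424; adjusted p = 0.296 with an estimated correlation), and after YAP/TAZ siRNA 3 fell and 0 rose (median -0.65, camera adjusted p = 0.0745). The gene that fell after BRD siRNA was MT1A, from 0.480 and 0.301 with control siRNA to between 0.0948 and 0.213. MT1A reached the filter limit of 1 only with JQ1 (2.61 and 2.88), so it entered the family through those libraries alone. MT2A was at 218 ± 27.7 scaled RPM with control siRNA (SD, n = 2), 126 ± 61.6 with YAP/TAZ siRNA (n = 4), 1099 ± 458 with BRD siRNA (n = 4), 291 ± 4.90 in DMSO (n = 2) and 1599 ± 125 with JQ1 (n = 2). The SDs over 4 libraries mostly reflect the mixes. MT2A was at 73.2 and 75.3 with YAP/TAZ siRNA mix 1 but 160 and 196 with mix 2. With BRD siRNA it was at 649 and 764 with mix A and 1546 and 1437 with mix B. MT1X had log2 fold changes of 2.59 after BRD siRNA and 3.78 after JQ1, while its -0.38 after YAP/TAZ siRNA averaged -0.997 with mix 1 and 0.24 with mix 2. The nuclear noncoding RNA NEAT1 rose after all 3 (2.30, 3.12 and 3.82), and so did MALAT1 (1.28, 1.23 and 3.18), but their mix A replicates stood apart, at 419 and 242 for NEAT1 and 5571 and 3292 for MALAT1.

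Of 80 ribosomal protein genes, 79 were higher in DMSO than with control siRNA (median 0.50, camera adjusted p = 4.7e-20; adjusted p = 0.293 with an estimated correlation). After YAP/TAZ siRNA 62 fell and 6 rose (median -0.29), after JQ1 38 fell and 13 rose (median -0.15), and after BRD siRNA 30 rose and 22 fell with a median of 0.03 whose sign changed with upper-quartile, quantile and no scaling. Of 129 small nucleolar RNA genes and hosts, 79 fell and 18 rose after YAP/TAZ siRNA, 73 fell and 8 rose after BRD siRNA, and 71 fell and 3 rose after JQ1, while 67 were higher and 1 lower in DMSO than with control siRNA.

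CTGF, CYR61 and ANKRD1, lower after YAP/TAZ siRNA, were higher after JQ1. Library scaling does not account for the rise, since the smallest log2 fold change of the 3 genes over the other scalings and count tests was 0.68. A low level in DMSO is argued against as well. The smallest ratio of the lower JQ1 library to the highest of the 4 control libraries was 1.65. More YAP1 or WWTR1 mRNA is argued against too, since the larger of their log2 fold changes was -0.33. Both comparisons were set after the results were seen, so they restate known values and are not independent tests. A rise of the whole target list is argued against only narrowly, with 10 of 22 members higher. An effect of BET inhibition on these genes apart from YAP and TAZ mRNA may remain as a hypothesis, and protein levels and localisation of YAP and TAZ are not analysed here.

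Interferon-stimulated genes had a negative median after BRD siRNA, although the list was not called. If an interferon response in the control siRNA libraries lay behind this, the list would be lower in DMSO than with control siRNA and not lower in BRD siRNA than in DMSO. Both held, with medians of -0.68 and 0.37, but the second is not a separate test. The list mean of BRD siRNA against DMSO (0.384) is that against control siRNA (-0.275) less that of DMSO against control siRNA (-0.659). A list that is lower in DMSO by more than after BRD siRNA must meet it. A response to transfection that differs between the control siRNA and the other groups may contribute, but these values do not decide it. Harvest times and the siRNA sequences also differ and were not tested.

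Genes at least 2-fold lower after both YAP/TAZ siRNA and JQ1 were more than independent lists give. A fall of cell cycle genes alone is argued against, since without 342 cell cycle and histone genes 341 genes were shared against 59.8, a ratio of 5.71. Joint calls of low genes are argued against too, since among genes above the median level 331 were shared against 57.3, a ratio of 5.78. Genes that follow slower growth without being in the cell cycle set may still make up part of the overlap, and growth was not measured in these files.

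The difference between YAP/TAZ and BRD siRNA was tested against other splits of the 8 knockdown libraries into 4 and 4. The real split gave 6472 genes in a model of 2 groups, against 96 for the highest other split, and 1 of 35 gave as many. Only 3 of the 35 keep the replicates of every mix together, too few for a share under 0.05, and the other 32 part replicates of a mix, so the count over all 35 does not decide.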
